A study of Mus musculus with 15 samples.

How the data were processed

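RNA was measured by sequencing in colon tissue from 15 mice in 3 groups of 5. All mice were given DSS (dextran sulfate sodium, a detergent-like polymer that injures the colon lining). DSS mice had nothing further by their label, DSS_ICB mice also had immune checkpoint blockade, and DSS_ICB_Fp mice also had a gavage of Faecalibacterium prausnitzii, a butyrate-making gut bacterium. The labels do not name the checkpoint antibodies, a control antibody, a control gavage or cages. Each file held 1 mouse and 1 value per gene. The numbers of the mice carry no match between groups, so no paired test was possible.

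Per the submitters' processing notes, the authors checked reads with FastQC, aligned them with STAR 2.5 to mm10, and made expression values with Cuffnorm, and DESeq was also named. The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) as the authors computed them. The unit was read from the tool named in those notes and from the values, which were not whole numbers and summed to between 341054 and 443338 per library. Whether a further scaling between libraries was applied is not stated. All 55335 genes in the files were identified by Ensembl IDs, of which 55154 matched a symbol in GENCODE release M21 on the GRCm38 assembly.

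The depth of each library is not stated with the values. It was estimated from the smallest steps between FPKM values of 34186 genes with 1 transcript, which gave 15.15 to 24.62 M (mega) fragments. These estimates hold only if no further scaling between libraries was applied. The group means were 18.4 ± 1.95 M in DSS, 19.5 ± 3.63 M in DSS_ICB and 19.1 ± 2.99 M in DSS_ICB_Fp (SD, n = 5). At the lowest depth, 1 FPKM for a transcript of 1 kilobase is about 15.2 fragments. Between 19.5% and 22.1% of low values fell within 0.03 log2 of a whole step, against 7.2% to 7.9% with shifted steps. Whole reads were therefore not recovered, and tests that need counts were not used.

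Genes with an FPKM of at least 1 in at least 5 libraries were tested, 14385 in all. Values were taken as log2(FPKM + 1), which understates the fold of genes with low values. limma 3.58.1 in R 4.3.3, with a trend in the prior variance and robust fitting, was fitted once to all 15 libraries with 1 mean per group. The 3 contrasts were DSS_ICB against DSS, DSS_ICB_Fp against DSS_ICB, and DSS_ICB_Fp against DSS. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. These choices, the gene lists, the rule for named genes and the alternatives were set before the data were examined, apart from those named as added.

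For gene groups, 38 lists with 725 entries were written down, of which 724 matched a gene, and 37 lists had at least 5 tested members. The exocrine pancreas list had too few. The list test was camera of limma with a preset correlation of 0.01 between genes, two-sided, adjusted over the 37 lists of a comparison. Beside it stand camera with an estimated correlation and fry of limma, a rotation test of whether the genes of a list move on balance in 1 direction. Members were also counted by adjusted p over all genes and adjusted over the list alone. A score per mouse, the mean of the members scaled to an SD of 1 over the 15 libraries, was compared by an exact two-sided permutation test over all 252 arrangements, whose smallest p is 0.00794.

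The rule for named genes took up to 8 higher and 8 lower genes with the largest change among those that passed, leaving out predicted gene models and means under 1 FPKM, or the 5 higher and 5 lower genes with the smallest p where none passed. It added the 3 members with the smallest p in the direction of each list that passed, and 24 genes fixed in advance. Genes named outside the rule were chosen after their values were seen, namely Angptl4, Bdkrb2, Car2, Col18a1, Csf3r, Entpd1, Gm14686, Gm22270, Ifitm1, Igha, Ighg1, Il1rl1, Isg15, Jchain, Jund, Lgi2, Nlrp6, Pigr, Slc16a3, Syt13, Tiparp, Tox and Wnt4. Xist was named as a marker of sex. For 3 of the lists, 1 gene that the rule names is not reported here.

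Alternatives were median-of-ratios and upper-quartile scaling, pseudocounts of 0.1 and 10, no filter, a filter at 5 FPKM, a fit of the 2 compared groups only, and leaving out each library in turn. Chosen after seeing the data were sample quality weights, the first principal component of the residuals as a covariate, rescaling without mitochondrially encoded genes, and leaving out DSS_ICB 3 and DSS_ICB 5 together. Those 2 libraries had median rank correlations with the others under 0.9. DESeq2, limma-voom with quality weights, a filter on CPM and surrogate variables by svaseq need counts and were not run on FPKM.

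The procedure was tested on simulated data with each gene's mean and spread, each gene drawn independently of the others. With 1 spread shared by the groups and no gene changed, 20 draws gave a median of 0 calls in each comparison. With each group's own spread they gave a median of 3 calls (0 to 11) for DSS_ICB against DSS, 2.5 (0 to 16) for DSS_ICB_Fp against DSS_ICB and 0 (0 to 1) for DSS_ICB_Fp against DSS. The fit of only 2 groups gave a median of 0 (0 to 1) in each. This simulation was added after the difference in spread between groups was seen. A further simulation with each group's own spread changed 50 genes each by 2-fold, 4-fold, 8-fold and 16-fold. Of the genes changed 4-fold, the shared fit recovered 94% for DSS_ICB against DSS and 98% for DSS_ICB_Fp against DSS_ICB. Wrong calls made up 23.5% and 15.5% of the calls over all 4 sizes. Only the T cell list, shifted by 1 log2 unit, passed the list test of 37 lists in each simulation. Since genes were drawn independently, this does not show how the list test behaves when members of a list move together.

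Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the depth estimate and the plots. No library and no column was left out of the main comparisons.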

Results

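Gene expression was measured by RNA sequencing of colon tissue from 15 mice, 5 each in the groups DSS, DSS_ICB and DSS_ICB_Fp. Between 13243 and 14336 genes per library had at least 1 FPKM, at estimated depths of 15.15 to 24.62 M (mega) fragments. Xist was at least 20.4 FPKM in every library and the 4 Y-linked genes checked were listed at 0, so sex did not differ between groups. The median rank correlation with the other libraries was 0.725 for DSS_ICB 3 and 0.864 for DSS_ICB 5, and the correlation was at least 0.888 for every pair of the other libraries. Mitochondrially encoded genes made up 33.2% of the FPKM in DSS_ICB 3, against 9.39% in DSS_ICB 2. The median SD of a gene on the log2 scale was 0.372 in DSS_ICB, 0.220 in DSS and 0.226 in DSS_ICB_Fp, and 68.5% of genes varied most in DSS_ICB.

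DSS_ICB against DSS asks what checkpoint blockade adds in mice given DSS. Since the labels name no control antibody or cage, the blockade cannot be told apart from the procedure of giving it or from the cage. No group without DSS was measured, so the effect of DSS itself is not shown here. Saa3, an acute-phase serum amyloid gene, rose from 0.616 ± 0.687 FPKM in DSS to 16.4 ± 10.7 FPKM in DSS_ICB (SD, n = 5), a log2 change of 3.28 ± 0.40 (SE, limma adjusted p = 0.00987). Mmp10, a matrix metalloproteinase, rose from 1.71 ± 0.746 to 11.8 ± 4.52 FPKM, a log2 change of 2.23 ± 0.32 (adjusted p = 0.034). Il11, a cytokine gene, rose from 0.510 ± 0.400 to 6.78 ± 3.83 FPKM, a log2 change of 2.21 ± 0.33 (adjusted p = 0.0352). For each of the 3 genes, which were chosen by their change, all 5 DSS_ICB libraries lay above all 5 DSS libraries.

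These 3 genes were higher and 0 were lower among 14385 tested with limma, while 1626 genes had an unadjusted p under 0.05 (1019 higher, 607 lower). Because DSS_ICB varied most, the shared spread understates errors here, and data simulated with each group's own spread and no change gave a median of 3 calls (0 to 11) and of 1048.5 genes at an unadjusted p under 0.05. With only these 2 groups in the fit, the 3 genes no longer passed (Saa3 adjusted p = 0.0594) and 1 other gene did, Gm14686, which was lower. Leaving out DSS 2, DSS 3 or DSS 4 left 0 genes (Saa3 adjusted p = 0.0647, 0.054 and 0.0565), and leaving out any other single library left only Saa3, except DSS_ICB 4, which gave 7 with Bdkrb2, Cxcl2, Il1r2 and Syt13 added. In the exclusions that ended their calls, adjusted p was 0.0561 to 0.135 for Mmp10 and 0.0654 to 0.17 for Il11. Over all alternatives adjusted p ranged from 0.000685 to 0.113 for Saa3, from 0.00111 to 0.219 for Mmp10 and from 0.000473 to 0.429 for Il11.

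Neutrophil genes moved up as a list in DSS_ICB, with a median log2 change of 1.92 over 12 tested members, all of them above 0 (list test adjusted p = 7.5e-13). Over all genes 0 passed, and 10 were higher adjusted over the list alone, with an adjusted p = 0.34 with an estimated correlation. S100a8 and S100a9, the subunits of calprotectin, had log2 changes of 3.47 ± 0.75 (adjusted p = 0.247) and 3.66 ± 0.81 (adjusted p = 0.254), and Il1r2, a decoy receptor, 2.03 ± 0.44 (SE). Inflammatory cytokines and chemokines had a median of 1.37 over 16 members (adjusted p = 1.8e-10), of which 1, Il11, passed over all genes and 12 were higher adjusted over the list alone. That list had an adjusted p = 0.34 with an estimated correlation. Its largest changes were in the neutrophil attractant Cxcl2, at 3.51 ± 0.68, and in Il1b, at 3.07 ± 0.63 (SE, adjusted p = 0.247 each). By fry both lists passed (adjusted p = 0.03 each). Of the 5 DSS_ICB mice, DSS_ICB 3 and DSS_ICB 5 had the highest neutrophil scores, 1.89 and 1.94, against 0.23 to 0.66 in the others, and without both the medians were 1.0 for neutrophil and 0.76 for inflammatory genes, which still passed the list test. Of the 16 lists that passed in this comparison, 9 did so without both mice, and the calls of the goblet cell, T cell, erythroid, small intestine, oxidative phosphorylation, immediate early and cholesterol lists ended.

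Fibroblast and matrix genes had a median of 0.65 over 22 members (adjusted p = 1.35e-12), with 1 passing over all genes (Mmp10) and 11 higher adjusted over the list alone, and an adjusted p = 0.401 with an estimated correlation. The collagenase Mmp13 and the stromelysin Mmp3 had changes of 1.85 ± 0.33 (adjusted p = 0.19) and 1.87 ± 0.46 (adjusted p = 0.348). Endothelial genes had a median of 0.69 and all 20 were above 0 (adjusted p = 1.35e-12), with 0 passing over all genes, 15 higher adjusted over the list alone, and an adjusted p = 0.401 with an estimated correlation. Plvap, Esam and Selp had values of 1.18, 0.85 and 1.28. The fetal-like repair list of the epithelium had a median of 0.65 over 16 members (adjusted p = 0.00014), with 0 and 7 higher, and an adjusted p = 0.422 with an estimated correlation. Spp1, Il33 and Ereg, a growth factor, had values of 2.30, 1.48 and 1.66. Erythroid genes, a marker of blood in the tissue, moved with these lists at a median of 1.78 over 7 members (adjusted p = 0.0111), with 0 and 5 higher, and an adjusted p = 0.466 with an estimated correlation. Hba-a2, Hba-a1 and Alas2 had values of 1.83, 1.86 and 1.02, and Hbb-bs was 326 and 386 FPKM in DSS_ICB 4 and DSS_ICB 5 against 43.7 in DSS_ICB 1. Without DSS_ICB 4 the erythroid list missed the threshold (adjusted p = 0.0533).

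T cell genes had a median of 0.44 over 9 members (adjusted p = 0.00603), with 0 passing over all genes, 0 adjusted over the list alone, and an adjusted p = 0.581 with an estimated correlation. Trbc2, Trac and Tcf7 had values of 0.70, 0.67 and 0.58, and the list missed the threshold without DSS_ICB 4 (adjusted p = 0.0509) or DSS_ICB 5 (adjusted p = 0.0838) and had a median of 0.72 without DSS_ICB 1. Dissociation and immediate early genes, which respond to tissue handling, had a median of 0.46 over 19 members (adjusted p = 0.000271), with 0 over all genes, 0 adjusted over the list alone, and an adjusted p = 0.466 with an estimated correlation. Ier3, Dusp1 and Myc had values of 1.43, 1.10 and 0.85, and without DSS 3 the median was 0.77.

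In the other direction, 8 lists were lower in DSS_ICB, with 0 members passing over all genes and 0 adjusted over the list alone in each. Absorptive colonocyte genes had a median of -0.92, with all 16 below 0 (adjusted p = 1.06e-06). The chloride exchanger Slc26a3 was 52.1 ± 12.8 FPKM in DSS and 17.1 ± 13.8 in DSS_ICB (SD, n = 5), a log2 value of -2.24 ± 0.74 (adjusted p = 0.418), and Selenbp1 and Slc26a2 had -1.98 and -1.22. Xenobiotic genes had a median of -0.93 over 19 members (adjusted p = 4.45e-05), with Sult1a1 at -1.77, Gstm3 at -1.64 and Gstm1 at -0.67, and small intestine genes -0.57 over 8 members (adjusted p = 0.00614), with Fabp6 at -1.57, Mep1a at -1.46 and Apob at -0.53. For these 3 lists the adjusted p = 0.466 with an estimated correlation. Junction genes had a median of -0.63 over 21 members (adjusted p = 9.5e-05; Cldn8 -1.61, Ocln -1.0, Marveld2 -0.75), goblet cell genes -0.52 over 17 (adjusted p = 0.000561; Atoh1 -1.18, Muc13 -0.99, Gfi1 -0.38) and cholesterol synthesis genes -0.50 over 20 (adjusted p = 4.78e-05; Stard4 -0.85, Msmo1 -0.71, Dhcr7 -0.69). Nuclear genes of oxidative phosphorylation had a median of -0.22 over 21 (adjusted p = 0.000236), with Uqcrc2 at -0.48, Sdha at -0.47 and Atp5b at -0.47. For these 4 lists the adjusted p = 0.581 with an estimated correlation. The butyrate transport and fatty acid oxidation list had a median of -0.26 over 21 members (adjusted p = 0.000391), with Ppargc1a at -1.02, Acadm at -0.48 and Hadhb at -0.44, and an adjusted p = 0.451 with an estimated correlation.

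DSS_ICB 3 set much of the size of those lower lists. Its colonocyte score was -2.99, against -0.29 to 0.10 in the other DSS_ICB mice, while its smooth muscle score was 2.59. Without DSS_ICB 3 the medians were -0.44 for absorptive colonocyte, -0.48 for xenobiotic and aryl hydrocarbon receptor, -0.22 for small intestine and proximal gut, -0.15 for epithelial junction and barrier, -0.09 for cholesterol synthesis and -0.12 for oxidative phosphorylation (nuclear) genes. The goblet cell and mucus list then missed the threshold (median -0.07, adjusted p = 0.0528), and its median was -0.88 without DSS_ICB 4. Without DSS_ICB 2 the medians were -0.33 for oxidative phosphorylation and -0.41 for the list of butyrate transport, sensing and fatty acid oxidation, and without DSS_ICB 5 oxidative phosphorylation had -0.13. In all, 16 of 37 lists passed the list test (8 higher, 8 lower), 0 with an estimated correlation, 2 by fry and 0 by the score per mouse (smallest exact permutation p = 0.00794, adjusted 0.0979).

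Of the genes fixed in advance that were tested, Tnf was 2.49 ± 1.01 FPKM in DSS and 6.47 ± 4.63 in DSS_ICB (SD, n = 5), a log2 value of 0.94 (limma adjusted p = 0.43). Lcn2, an antimicrobial siderophore-binding protein, had 1.67 (adjusted p = 0.381), Cd274, which encodes PD-L1, 0.59 (adjusted p = 0.537), Gzmb 0.53 (adjusted p = 0.482) and Cxcl10 0.10 (adjusted p = 0.919). Muc2 had -0.84 (adjusted p = 0.56), Lgr5 -0.24 (adjusted p = 0.67), Tjp1 -0.11 (adjusted p = 0.752) and Ffar2 -0.07 (adjusted p = 0.867). The Muc2 value rested on DSS_ICB 3, with 13.0 FPKM against 149.9 to 259.9 in the other DSS_ICB mice, and was -0.07 without it. Without DSS_ICB 3, Slc26a3 had -1.47, Ocln -0.46, Lgr5 -0.14, Tjp1 -0.03, Ffar2 -0.01, Cd274 0.37 and Cxcl10 -0.02. Without DSS_ICB 5, Lgr5 had -0.14, Tjp1 -0.22, Cd274 0.26, Gzmb 0.27 and Cxcl10 -0.21. Below the filter, and not tested, Il6 was 0.147 FPKM in DSS, 1.08 in DSS_ICB and 0.0436 in DSS_ICB_Fp, Ctla4 was 0.624, 1.57 and 0.586, and Foxp3 was 0.167, 0.464 and 0.168. Il22 was 3.59 FPKM in DSS_ICB, where 1 library, DSS_ICB 5, had 17.8, against 0.13 in DSS and 0.0107 in DSS_ICB_Fp. Cd8a, Pdcd1, Cxcl9, Ifng, Il17a, Il10 and Reg3g were also below the filter, at 0.568, 0.691, 0.922, 0.0644, 0.331, 0.677 and 0.255 FPKM in DSS_ICB.

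**Figure D1:**
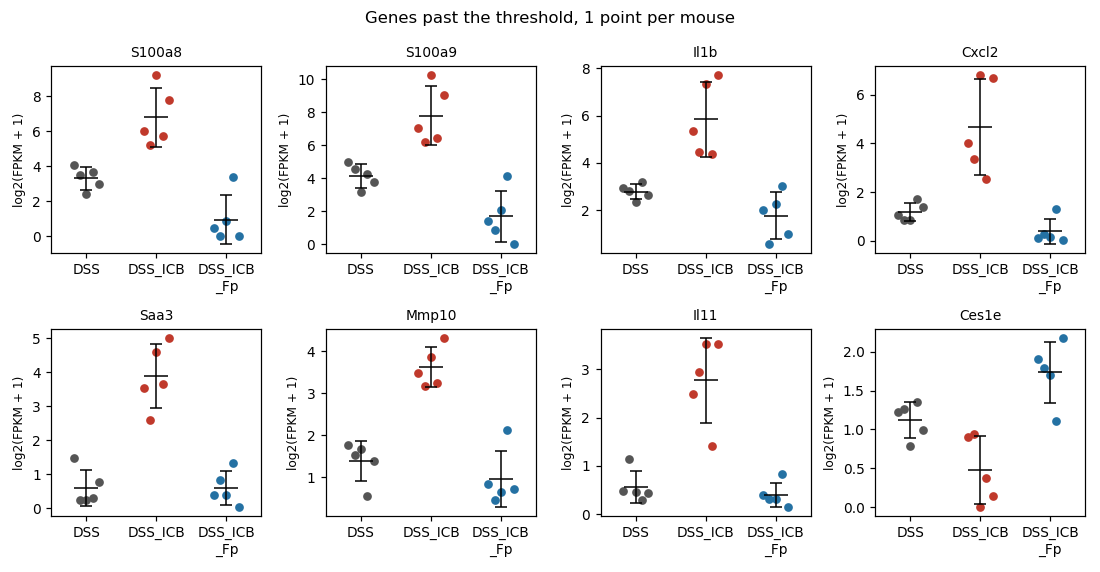
Expression of 8 genes in each mouse as log2(FPKM + 1), by group, with points for the 5 mice of a group and bars for the mean ± SD. Saa3, Mmp10 and Il11 in all 5 DSS_ICB mice lie above all 5 DSS mice, and S100a8 ranges from 35.3 to 592.8 FPKM within DSS_ICB.

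DSS_ICB_Fp against DSS_ICB asks what the bacterial gavage changes in mice given DSS and checkpoint blockade. With no control gavage or cage in the labels, the bacterium cannot be told apart from the gavage procedure or the cage. The calprotectin genes fell in gavaged mice, S100a9 from 408 ± 494 to 4.41 ± 6.78 FPKM (SD, n = 5), a log2 change of -6.10 ± 0.81 (SE, limma adjusted p = 0.00702), and S100a8 from 193 ± 235 to 2.10 ± 4.04 FPKM, a log2 change of -5.85 ± 0.75 (adjusted p = 0.0061). Saa3 fell to 0.593 ± 0.592 FPKM (-3.29 ± 0.40, adjusted p = 0.00481), Mmp10 to 1.14 ± 1.24 FPKM (-2.65 ± 0.32, adjusted p = 0.00481) and Il11 to 0.336 ± 0.254 FPKM (-2.37 ± 0.33, adjusted p = 0.00934). Il1b fell from 90.2 ± 89.1 to 3.05 ± 2.65 FPKM (-4.09 ± 0.63, adjusted p = 0.0229) and Cxcl2 from 48.8 ± 53.7 to 0.383 ± 0.618 FPKM (-4.30 ± 0.68, adjusted p = 0.0229). Ces1e, a carboxylesterase, rose from 0.442 ± 0.434 to 2.43 ± 0.857 FPKM (1.26 ± 0.22, adjusted p = 0.034). Within DSS_ICB_Fp, S100a8 was listed at 0 in mice 2 and 5, and was 0.389, 0.812 and 9.30 FPKM in mice 1, 3 and 4.

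Also lower were Retnlg (-3.52 ± 0.56, adjusted p = 0.0229) and Clec4d (-2.67 ± 0.46, adjusted p = 0.034), which neutrophils express, the matrix metalloproteinases Mmp3 (-2.67 ± 0.46, adjusted p = 0.034) and Mmp13 (-2.07 ± 0.33, adjusted p = 0.0229), and the chemokine Ccl22 (-1.19 ± 0.20, SE, adjusted p = 0.0272). The remaining 6 lower genes, chosen after their values were seen, were Csf3r (-2.59), Ifitm1 (-2.0), Lgi2 (-1.66), Col18a1 (-1.30), Wnt4 (-1.16) and Gm22270 (-1.03). On GRCm38, S100a8 (ENSMUSG00000056054) lies on chromosome 3 from 90668978 to 90670035 and S100a9 (ENSMUSG00000056071) from 90692632 to 90695721. Saa3 (ENSMUSG00000040026) lies on chromosome 7 from 46711998 to 46715700, Il11 (ENSMUSG00000004371) on chromosome 7 from 4772373 to 4782859, and Mmp10 (ENSMUSG00000047562) on chromosome 9 from 7502352 to 7510240. Il1b (ENSMUSG00000027398) lies on chromosome 2 from 129364570 to 129371139, Cxcl2 (ENSMUSG00000058427) on chromosome 5 from 90903871 to 90905938, and Ces1e (ENSMUSG00000061959) on chromosome 8 from 93201218 to 93229619. Reads shared between close copies make the split between Hba-a1 and Hba-a2, between Trbc1 and Trbc2 and within the Ces1 family uncertain.

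With limma, 1 gene was higher and 18 were lower of 14385, and 3129 had an unadjusted p under 0.05 (1344 higher, 1785 lower). The shared spread understates errors here too. Simulated data with each group's own spread and no change gave a median of 2.5 calls (0 to 16) and of 1093 genes at an unadjusted p under 0.05, and with only these 2 groups in the fit 0 genes passed (smallest adjusted p = 0.0815, with 2343 at p under 0.05). The count rose to 598 (228 higher, 370 lower), 153 (32 and 121) and 75 (2 and 73) without DSS_ICB 1, DSS_ICB 2 and DSS_ICB 4 and to 449 (123 and 326) without DSS_ICB_Fp 4, each with all 19 genes included. It fell to 9 and 8 without DSS_ICB 3 and DSS_ICB 5, to 6 without DSS_ICB_Fp 1, and to 5 without DSS_ICB_Fp 2, DSS_ICB_Fp 3 or DSS_ICB_Fp 5. S100a8, S100a9, Saa3 and Mmp10 passed in 20 of 21 alternatives, all but the fit of 2 groups (adjusted p = 0.126, 0.126, 0.0815 and 0.0815), and Il11 in 18 of 20. The other 8 named genes passed in 9 to 13 of their alternatives, and each missed the threshold without DSS_ICB_Fp 1, DSS_ICB_Fp 2, DSS_ICB_Fp 3 or DSS_ICB_Fp 5 (0.0583 to 0.134; for Il1b adjusted p = 0.0699, 0.0713, 0.0583 and 0.0861). Without DSS_ICB 3 the calls of Il1b, Mmp13, Clec4d and Ccl22 (adjusted p = 0.0574 each), Mmp3 (0.0724) and Ces1e (0.0717) ended. Without DSS_ICB 5 those of Cxcl2 (0.0546), Retnlg (0.0766), Clec4d (0.0909), Mmp3 and Ces1e (0.114 each) ended. The highest adjusted p over the alternatives was 0.176 for Mmp3 and 0.216 for each of the other 7, in the fit of 2 groups.

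Neutrophil genes had a median log2 change of -2.48 in gavaged mice, with all 12 below 0 (list test adjusted p = 4.78e-13). Of these 5 fell over all genes and 10 adjusted over the list alone, with an adjusted p = 0.361 with an estimated correlation. Inflammatory cytokines and chemokines had a median of -2.06 over 16 members (adjusted p = 4.16e-10), of which 3 fell over all genes (Il11, Il1b, Cxcl2) and 13 adjusted over the list alone. Fibroblast and matrix genes had -0.94 over 22 (adjusted p = 5.95e-14), with 3 over all genes (Mmp10, Mmp13, Mmp3) and 19 adjusted over the list alone. For both lists the adjusted p = 0.361 with an estimated correlation. Endothelial genes had a median of -0.79 over 20 (adjusted p = 4.16e-10), with 0 over all genes and 18 adjusted over the list alone, and Selp, Pecam1 and Esam had -1.43, -0.92 and -0.79. The fetal-like repair list had -0.83 over 16 (adjusted p = 2.8e-05), with 0 and 8, and Spp1, Ereg and Il33 had -2.45, -2.23 and -1.83. Each of these had an adjusted p = 0.361 with an estimated correlation. By fry these 5 lists passed, with adjusted p = 0.00393, 0.00393, 0.00781, 0.0285 and 0.0175 in the order given. Without DSS_ICB 3 and DSS_ICB 5 the medians were -1.51 for neutrophil, -1.28 for inflammatory and -0.61 for matrix genes, which still passed the list test. Of the 20 lists that passed in this comparison, 13 did so without both mice, and the calls of the B cell, dendritic cell, erythroid, small intestine, oxidative phosphorylation, immediate early and cholesterol lists ended.

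Among other immune lists, T cell genes had a median of -0.80 over 9 members (adjusted p = 0.000248), with 0 over all genes, 4 lower adjusted over the list alone, and an adjusted p = 0.39 with an estimated correlation. Trbc2, Trbc1 and Tcf7 had -1.04, -0.86 and -0.80. Monocyte and macrophage genes had -0.48 over 21 (adjusted p = 0.00123), with 0 over all genes and 1 adjusted over the list alone (Vcan -1.20, adjusted p = 0.0515 over all genes), and an adjusted p = 0.495 with an estimated correlation. Cd68 and Fcgr3 had -1.0 and -0.89, and without DSS_ICB 5 the median was -0.24. Dendritic cell genes had -0.34 over 9 (adjusted p = 0.0103), with 1 over all genes (Ccl22), 3 adjusted over the list alone, and an adjusted p = 0.39 with an estimated correlation. Ccr7 and Fscn1 had -1.36 and -0.88, and without DSS_ICB 5 the list missed the threshold (median -0.11, adjusted p = 0.0508). B cell and plasma cell genes had -1.21 over 18 (adjusted p = 0.00564), with 0 over all genes, 0 adjusted over the list alone, and an adjusted p = 0.616 with an estimated correlation. The B cell genes Cd79a, Cd79b and Pax5 had -2.70, -2.09 and -1.42. The antibody genes Jchain (1.39), Igha (1.13) and Ighg1 (0.24), chosen after their values were seen, lay above 0 and did not pass, so the fall of the list does not extend to these genes. Igha was 522.5 FPKM in DSS_ICB_Fp 5, against 40.3 to 211.2 in the other gavaged mice, and 11.7 in DSS_ICB 3. Without DSS_ICB_Fp 4 the list missed the threshold (adjusted p = 0.114).

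Erythroid genes had a median of -2.31 over 7 members (adjusted p = 0.0165), with 0 over all genes, 5 lower and 1 higher adjusted over the list alone, and an adjusted p = 0.39 with an estimated correlation. Hba-a2, Hba-a1 and Hbb-bs had -2.34, -2.32 and -2.32, the higher member was the carbonic anhydrase Car2, which colon epithelium also expresses (1.5), and without DSS_ICB_Fp 4 the list missed the threshold (adjusted p = 0.0514). Immediate early genes had -0.74 over 19 (adjusted p = 0.000227), with 0 over all genes, 10 lower and 1 higher (Jund) adjusted over the list alone, and an adjusted p = 0.39 with an estimated correlation. Ier3, Egr2 and Hsph1 had -1.72, -1.06 and -0.59.

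By the list test 9 lists, among them epithelial and metabolic ones, were higher in gavaged mice, while the fetal-like repair list of the epithelium was lower. Absorptive colonocyte genes had a median of 1.11 over 16 members (adjusted p = 2.7e-06), with 0 over all genes, 7 higher adjusted over the list alone, and an adjusted p = 0.39 with an estimated correlation. Slc26a3 was 91.4 ± 57.8 FPKM in DSS_ICB_Fp (SD, n = 5), a log2 value of 2.82 ± 0.74 (limma adjusted p = 0.0862), and Selenbp1 and Car4 had 2.58 and 1.65. Xenobiotic genes had 1.03 over 19 (adjusted p = 3.45e-07), with 0 over all genes, 11 higher and 1 lower (Tiparp) adjusted over the list alone. The sulfotransferase Sult1a1, the glucuronosyltransferase Ugt1a1 and Gstm1 had 2.5, 2.03 and 1.03. The butyrate transport and fatty acid oxidation list had 0.33 over 21 (adjusted p = 0.00018), with 0 over all genes, 9 higher adjusted over the list alone, among them Acads (1.22), the butyrate transporter gene Slc16a1 (1.04) and Acadm (0.71), and 2 lower, Angptl4 and the lactate exporter Slc16a3. For both lists the adjusted p = 0.361 with an estimated correlation.

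Goblet cell genes had a median of 0.84 over 17 members (adjusted p = 4.84e-05, and adjusted p = 0.421 with an estimated correlation), with Atoh1 at 1.85, Bcas1 at 1.13 and Gfi1 at 0.54. Junction genes had 0.75 over 21 (adjusted p = 0.00018, and adjusted p = 0.495 with an estimated correlation), with Cldn8 at 1.70, Cldn15 at 1.22 and Cldn3 at 0.90. Oxidative phosphorylation genes had 0.41 over 21 (adjusted p = 9.45e-06, and adjusted p = 0.418 with an estimated correlation), with Sdha at 0.58, Atp5c1 at 0.45 and Ndufv1 at 0.39. Cholesterol synthesis genes had 0.40 over 20 (adjusted p = 0.00123, and adjusted p = 0.61 with an estimated correlation), with Dhcr7 at 0.75 and Stard4 at 0.71. In these 4 lists 0 genes passed over all genes and 0 adjusted over the list alone. Small intestine genes had 0.94 over 8 (adjusted p = 0.00469) and distal Hox genes 0.35 over 10 (adjusted p = 0.0103), with 0 over all genes, and 3 and 1 higher adjusted over the list alone. For both the adjusted p = 0.39 with an estimated correlation, and Fabp6, Mep1a and Apob had 1.91, 1.73 and 0.88, and Hoxb13, Hoxb9 and Hoxd12 1.51, 0.99 and 0.59.

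As in the comparison with DSS, DSS_ICB 3 set much of these sizes, and without it the medians were 0.58 for absorptive colonocyte, 0.37 for goblet cell and mucus, 0.20 for epithelial junction and barrier, 0.35 for small intestine and proximal gut and 0.26 for oxidative phosphorylation (nuclear) genes. The cholesterol synthesis list then missed the threshold (median 0.04, adjusted p = 0.16), and without DSS_ICB 5 the distal hindgut Hox median was 0.23. In all, 20 of 37 lists passed the list test (9 higher, 11 lower), 0 with an estimated correlation, 5 by fry and 0 by the score per mouse (smallest exact permutation p = 0.00794, adjusted 0.0588). Of the remaining genes fixed in advance, Lcn2 had -2.0 (limma adjusted p = 0.0754), Tnf -1.46 (adjusted p = 0.0802), Cd274 -1.0 (adjusted p = 0.172), Gzmb -0.65 (adjusted p = 0.226) and Cxcl10 -0.54 (adjusted p = 0.354). Muc2 had 1.18 (adjusted p = 0.262), Ocln 0.99 (adjusted p = 0.213), Lgr5 0.49 (adjusted p = 0.232), Ffar2 0.04 (adjusted p = 0.907) and Tjp1 0.03 (adjusted p = 0.919). Without DSS_ICB 3, Muc2 had 0.42, Ocln 0.45, Tjp1 -0.06 and Ffar2 -0.02, and without DSS_ICB 5, Tjp1 had 0.14, Cd274 -0.66, Gzmb -0.39 and Cxcl10 -0.24.

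**Figure D2:**
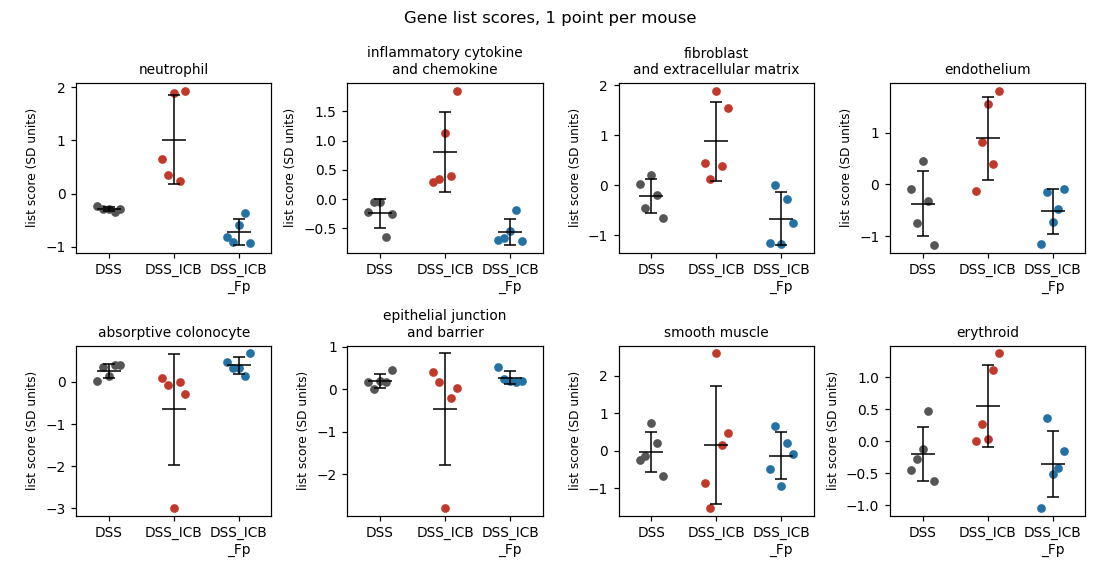
Scores of 8 gene lists in each mouse, as the mean of the members scaled to an SD of 1 over the 15 libraries, with points for the 5 mice of a group and bars for the mean ± SD. DSS_ICB 3 has a colonocyte score of -2.99 and DSS_ICB 3 and DSS_ICB 5 have neutrophil scores of 1.89 and 1.94.

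DSS_ICB_Fp against DSS asks whether gavaged mice still differed from mice without checkpoint blockade. No single gene was distinguished between the groups, while the levels of neutrophil genes in gavaged mice lay below those of DSS mice by value. S100a9 was 18.4 ± 8.87 FPKM in DSS and 4.41 ± 6.78 in DSS_ICB_Fp, and S100a8 was 9.76 ± 4.51 and 2.10 ± 4.04 (SD, n = 5), with log2 values of -2.44 ± 0.81 and -2.38 ± 0.75 (SE, limma adjusted p = 1 each). The B cell receptor gene Cd79a was 22.1 ± 14.5 and 7.36 ± 12.2 FPKM (log2 value -2.08 ± 0.97). Its values crossed between the groups. DSS 5 had 1.19 FPKM, against 16.3 to 40.2 in the other DSS mice, and DSS_ICB_Fp 5 had 28.7, against 0.288 to 6.25 in the other gavaged mice.

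With limma, 0 of 14385 genes passed (smallest adjusted p = 0.9997), 203 had an unadjusted p under 0.05 (85 higher, 118 lower), where simulated data with each group's own spread and no change gave a median of 407.5, and 0 passed in the fit of only these 2 groups, with 632 at p under 0.05 (smallest adjusted p = 0.923). The spread shared with DSS_ICB overstates errors here, so this count does not show that the groups were alike. By the rule for comparisons with no gene passing, the smallest p among higher genes belonged to Bex4 (0.76), Smim27 (0.44), Usp2 (0.65), Snord89 (0.60) and Gpt (0.54), and among lower genes to Tnpo3 (-0.44), Rfx5 (-0.51), Zfp930 (-0.36), Nudt6 (-0.41) and Snord53 (-0.66), none past the threshold.

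By the list test 17 of 37 lists passed (6 higher, 11 lower), with 0 members passing over all genes and 0 adjusted over the list alone in each, 0 lists with an estimated correlation, 0 by fry and 0 by the score per mouse (smallest exact permutation p = 0.00794, adjusted 0.294). Proliferation genes had a median of -0.55, with all 21 below 0 (adjusted p = 2.43e-07), with Cdk1 at -0.69, Mcm3 at -0.60 and Cenpf at -0.51. B cell and plasma cell genes had -0.92 over 18 (adjusted p = 5.91e-06), with Fcer2a at -1.40 and Fcrla at -0.90, while Igha (0.55), Ighg1 (0.37) and Jchain (0.24) lay above 0. The scores of this list crossed between the groups, with -0.90 in DSS 5 and 1.11 in DSS_ICB_Fp 5. Fibroblast and matrix genes had -0.26 over 22 (adjusted p = 1.82e-05), with Mmp3 at -0.79, Col6a3 at -0.47 and Col3a1 at -0.38, and neutrophil genes -0.50 over 12 (adjusted p = 3.53e-05), with Retnlg at -1.06. Monocyte and macrophage genes had -0.35 over 21 (adjusted p = 0.000895), with Cd68 at -0.57, Fcgr3 at -0.55 and Vcan at -0.47, and dendritic cell genes -0.23 over 9 (adjusted p = 0.00244), with Ccr7 at -0.96, Cd83 at -0.61 and Ccl22 at -0.60. For each of these 6 lists the adjusted p = 0.618 with an estimated correlation. Medians moved to -0.36 for proliferation without DSS_ICB_Fp 5, to -0.39 for fibroblast and extracellular matrix without DSS_ICB_Fp 2 and to -0.15 for dendritic cell genes without DSS_ICB_Fp 1.

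Type I interferon genes had a median of -0.28 over 20 members (adjusted p = 0.000641, and adjusted p = 0.618 with an estimated correlation), with Rtp4 at -0.63, Zbp1 at -0.62 and Irf7 at -0.32. Interferon gamma and antigen presentation genes had -0.25 over 28 (adjusted p = 0.000774, and adjusted p = 0.66 with an estimated correlation), with H2-Aa at -0.67, H2-Eb1 at -0.60 and H2-DMb1 at -0.46. Inflammatory genes had -0.36 over 16 (adjusted p = 0.00472), with Cxcl5 at -1.10, Il1b at -1.02 and Cxcl1 at -0.60. T cell genes had -0.31 over 9 (adjusted p = 0.00793), with Cd4 at -0.38 and Trbc1 and Trbc2 at -0.34 each, and the fetal-like repair list -0.31 over 16 (adjusted p = 0.0234), with Areg at -0.60 and Anxa1 at -0.40. For these 3 lists the adjusted p = 0.618 with an estimated correlation. In DSS 3 alone Isg15 reached 33.6 FPKM, and without DSS 3 the type I interferon response (-0.05, adjusted p = 0.522) and the interferon gamma response and antigen presentation (-0.08, adjusted p = 0.183) missed the threshold. They also missed it without DSS_ICB_Fp 4 (adjusted p = 0.0609 and 0.117) and had medians of -0.42 and -0.39 without DSS_ICB_Fp 1. The inflammatory cytokine and chemokine list missed it without DSS 2 (adjusted p = 0.059) and had -0.57 without DSS_ICB_Fp 4. T cell genes missed it without DSS 1, DSS 3, DSS_ICB_Fp 2 or DSS_ICB_Fp 4 (adjusted p = 0.0565, 0.0681, 0.0965 and 0.0884), and fetal-like repair epithelium without DSS 2, DSS 3, DSS_ICB_Fp 3 or DSS_ICB_Fp 5 (adjusted p = 0.299, 0.0916, 0.0975 and 0.162).

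Higher lists were xenobiotic genes with 0.31 over 19 (adjusted p = 0.000641), with Ugt1a1 at 1.0, Ces1g at 0.39 and Gstm1 at 0.36, and adipocyte genes with 0.30 over 11 (adjusted p = 0.00854), with Pck1 at 0.85, Retn at 0.83 and Adipoq at 0.80. Crypt base genes had 0.19 over 15 (adjusted p = 0.0155), with Ascl2 at 0.59, Ephb3 at 0.33 and Znrf3 at 0.28, and distal Hox genes had 0.11 over 10 (adjusted p = 0.0234), with Hoxd10 at 0.63, Hoxb9 at 0.29 and Hoxd12 at 0.25. For these 4 lists the adjusted p = 0.618 with an estimated correlation. Goblet cell genes had 0.23 over 17 (adjusted p = 0.0186), with Atoh1 at 0.67, Tff3 at 0.48 and Creb3l1 at 0.31, and oxidative phosphorylation genes 0.09 over 21 (adjusted p = 0.00793), with Cox5b at 0.26 and Ndufb8 at 0.20, each with an adjusted p = 0.772 with an estimated correlation. The goblet cell and mucus list missed the threshold without DSS 1, DSS 3, DSS_ICB_Fp 1 or DSS_ICB_Fp 4 (adjusted p = 0.236, 0.0652, 0.0765 and 0.0609). The oxidative phosphorylation (nuclear) list missed it without DSS 1, DSS 3 or DSS_ICB_Fp 4 (adjusted p = 0.0797, 0.0652 and 0.103). Adipocyte genes missed it without DSS 2, DSS 5, DSS_ICB_Fp 2 or DSS_ICB_Fp 5 (adjusted p = 0.0588, 0.0902, 0.139 and 0.258), and distal hindgut Hox genes did without DSS 1, DSS 5, DSS_ICB_Fp 1 or DSS_ICB_Fp 2 (adjusted p = 0.124, 0.0678, 0.209 and 0.0633). The Hox median was 0.05 without DSS 2, 0.17 without DSS 3 and 0.19 without DSS_ICB_Fp 4. Medians moved to 0.35 for goblet cell and 0.46 for adipocyte genes without DSS 4 and to 0.51 for adipocyte genes without DSS_ICB_Fp 1. They moved to 0.09 and 0.13 for crypt base and stem cell genes without DSS 2 and DSS 5, and to 0.13 for xenobiotic and aryl hydrocarbon receptor genes without DSS_ICB_Fp 5.

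The remaining genes fixed in advance had log2 values of 0.58 (Slc26a3), 0.35 (Muc2), 0.25 (Lgr5), -0.01 (Ocln), -0.03 (Ffar2), -0.08 (Tjp1), -0.12 (Gzmb), -0.33 (Lcn2), -0.41 (Cd274), -0.45 (Cxcl10) and -0.52 (Tnf).

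**Figure D3:**
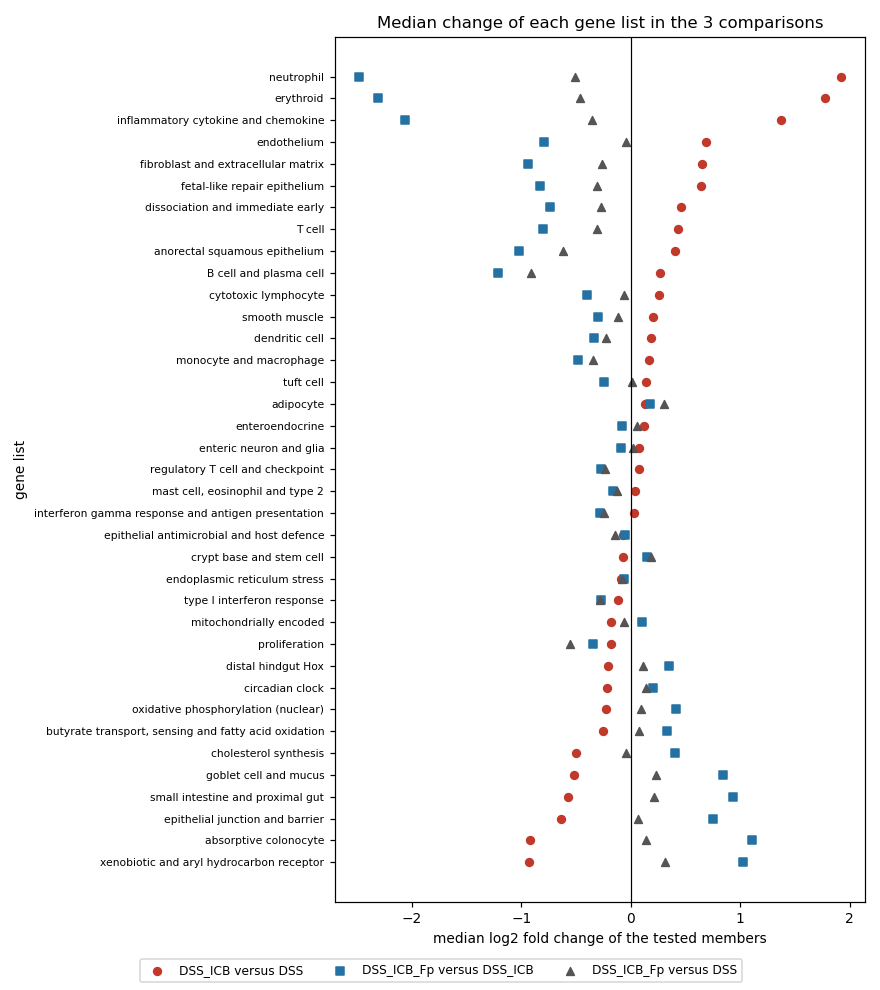
Median log2 change of the tested members of each of 37 gene lists in the 3 comparisons. Neutrophil genes lie at 1.92, -2.48 and -0.50, and absorptive colonocyte genes at -0.92, 1.11 and 0.14, for DSS_ICB against DSS, DSS_ICB_Fp against DSS_ICB and DSS_ICB_Fp against DSS.

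The directions of the changes with checkpoint blockade and with the gavage were compared. All 3 genes that passed in DSS_ICB against DSS (100%) moved the other way in DSS_ICB_Fp against DSS_ICB, as did all 335 genes with an unadjusted p under 0.01. Both comparisons share the DSS_ICB libraries, which alone makes their changes oppose each other, and simulated data with unchanged groups gave 88.6% opposite on average and up to 100%. The covariance of the log2 changes over all genes was -0.164, and 59 of 1000 simulations with unchanged groups were at or below it. In a further simulation, which used each library's residuals once with random signs, 25 of 1000 were. With DSS_ICB libraries divided between the comparisons, 20 divisions gave 83.5% opposite on average (49.0% to 95.9%).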

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

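For the library DSS_ICB 3, the test of sequencing depth and the test of muscle against mucosa were chosen after the result was seen. A library was picked out here when its gap to the nearest other library of its group was more than 0.71 of the group's range, which chance gives in about 1 of 20 groups. Of 507 tests on 128 genes, 37 list scores and library measures, 37 were picked out, where chance gives 25.4, so most single flags are no more than chance gives. DSS_ICB 3 had 12 of them, DSS_ICB_Fp 4 had 9, DSS 3 had 4, DSS 2 and DSS_ICB 5 had 3 each, DSS 5 had 2, and DSS 4, DSS_ICB_Fp 1, DSS_ICB_Fp 3 and DSS_ICB_Fp 5 had 1 each.

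In DSS_ICB 3 the scores were low for absorptive colonocyte (-2.99), epithelial junction and barrier (-2.80), small intestine and proximal gut (-2.43), proliferation (-2.31), endoplasmic reticulum stress (-1.62) and epithelial antimicrobial and host defence (-1.37) genes. On the log2(FPKM + 1) scale its values were low for Muc2 (3.81), Muc13 (6.06), Ocln (1.48, others at least 3.85), Mep1a (0.98), Car4 (4.34) and Mcm3 (2.19). If no further scaling between libraries was applied, low sequencing depth is argued against, since its estimated depth was 73.5% of the mean of the other 4 DSS_ICB libraries. DSS 1, at 16.47 M (mega) fragments against 15.15 M in DSS_ICB 3, had a median rank correlation of 0.946 with the others. A candidate explanation is a piece of tissue with less mucosa and more muscle wall. Against the other 4, its smooth muscle genes were higher by a median of 2.69 and its enteric neuron genes by 1.47, the lower of which was the value tested, and 5 of 6 epithelial lists were below 0, with a median of -1.87. Against the same 4 libraries, DSS_ICB 3 also had medians of 1.91 for neutrophil, 1.01 for inflammatory and 0.91 for matrix genes. Monocyte and macrophage genes had -1.22. The test of muscle against mucosa did not use these lists. No biological explanation was tested for a single mouse, and loss of mucosa through disease stays open.

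DSS_ICB_Fp 4 had the lowest mitochondrial share of its group (16.8%, others 19.6% to 20.4%) and a high fetal-like repair score (0.25). Its log2(FPKM + 1) values were high for S100a8 (3.36), Mmp10 (2.12), Cxcl2 (1.31) and Selp (1.55), and low for Cldn8 (6.01), Hadhb (3.92) and Hoxb9 (3.92).

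DSS_ICB 5 had high scores for fetal-like repair genes (1.51) and for mast cell, eosinophil and type 2 genes (1.23), and a high Selp value (3.54). DSS 3 had a high dissociation and immediate early score (1.13), a high Dusp1 value (5.11) and low values of Gstm3 (2.72) and Msmo1 (4.36). DSS 2 had a low crypt base and stem cell score (-0.68) and high values of Il11 (1.15) and Fcgr3 (4.19). DSS 5 had low values of the B cell genes Cd79b (0.73) and Fcrla (0.25). DSS_ICB_Fp 1 had a high junction score (0.53), DSS_ICB_Fp 3 a high Egr2 value (0.85), DSS_ICB_Fp 5 a low Atp5c1 value (7.38) and DSS 4 a low Cenpf value (1.87).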

How the results depend on the processing

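Sample quality weights, the residual component, rescaling without mitochondrial genes and the exclusion of DSS_ICB 3 and DSS_ICB 5 together were chosen after the result was seen. Values of the named genes and of the list scores with the smallest permutation p were compared over the alternatives. Of these, 3893 kept their direction and their side of the threshold, 118 kept direction and no longer passed, 168 kept direction and newly passed, and 26 turned direction or sign. The 3893 include genes that did not pass in the main fit, while the 118 all come from results that passed there. Il11 in DSS_ICB against DSS, for example, passed in 3 of 20 alternatives. For DSS_ICB against DSS the count of genes (3) was 1 with upper-quartile scaling, a pseudocount of 10, no filter, a filter at 5 FPKM or the 2 groups alone, 0 with a pseudocount of 0.1, and 0 to 7 leaving out 1 library. For DSS_ICB_Fp against DSS_ICB the count (19) was 42 with a pseudocount of 0.1, 5 with 10, 7 with no filter, 11 with a filter at 5 FPKM, 0 with the 2 groups alone, and 5 to 598 leaving out 1 library. In these comparisons quality weights gave 2 and 964 (221 higher, 743 lower), and the residual component gave 1512 (645 higher, 867 lower) and 2870 (1522 higher, 1348 lower). The residual component is fitted to the residuals themselves, so it shrinks the spread by construction, and neither fit replaces the counts above. For the other changes the cause was not tested. For DSS_ICB_Fp against DSS every alternative gave 0 genes, with 1221 at an unadjusted p under 0.05 with quality weights. Without DSS_ICB 3 and DSS_ICB 5 the counts were 2 (1 shared, the other Spp1), 21 (13 shared) and 0. The lists that passed were then 15 (9 shared with 16), 19 (13 shared with 20) and 19 (17 shared with 17), so 7 list calls ended in each comparison with DSS_ICB.

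Lists that passed were 0, 0 and 0 with an estimated correlation and 2, 5 and 0 by fry, in the order of the comparisons. Those tests allow for correlation between genes or test each list on its own. Why fewer lists passed with them was not tested. The share of opposite genes was 83.5% on average with DSS_ICB libraries divided between comparisons.

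Single genes that did not pass turned direction, some from values near 0 and others, such as Cd274 (0.59) and Muc2 (-0.84) in DSS_ICB against DSS and Stard4 (0.71) in DSS_ICB_Fp against DSS_ICB, from far from it. Cd274, Muc2 and Stard4 turned only without DSS_ICB 3 and DSS_ICB 5 together, so their directions rested on these libraries. In DSS_ICB 3 and DSS_ICB 5, Cd274 was 9.17 and 13.0 FPKM, against 1.52 to 3.58 in the other DSS_ICB mice. Stard4 was 5.58 and 17.2 FPKM, against 29.6 to 45.4. For the other genes the cause was not tested. For DSS_ICB against DSS, Cxcl10 had -0.25 with quality weights, and without DSS_ICB 3 and DSS_ICB 5 Cxcl10 had -0.47, Cd274 -0.15, Muc2 0.0641, Lgr5 0.0335 and Ffar2 0.00268. For DSS_ICB_Fp against DSS_ICB, Ffar2 had -0.0419 with quality weights, and without those libraries Ffar2 had -0.0340, Stard4 -0.0258 and Cxcl10 0.0208. For DSS_ICB_Fp against DSS, Ocln had 0.00455 with median-of-ratios scaling and 0.0516 with quality weights. Leaving out 1 library, Cxcl10 ranged from -0.21 to 0.31 in DSS_ICB against DSS, Tjp1 from -0.0571 to 0.14 and Ffar2 from -0.0453 to 0.14 in DSS_ICB_Fp against DSS_ICB, and Ocln from -0.11 to 0.14, Ffar2 from -0.12 to 0.0697 and Gzmb from -0.25 to 0.0622 in DSS_ICB_Fp against DSS.

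Quality weights were 0.111 for DSS_ICB 3, 0.455 for DSS_ICB 5 and 0.551 for DSS_ICB_Fp 4. DESeq2, limma-voom with quality weights, a filter on CPM and svaseq were not run, since they need counts. At the lowest estimated depth 1 FPKM of a transcript of 1 kilobase is about 15.2 fragments.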

Other observations

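The tests of a lower share of epithelium, of the tie between neutrophil and matrix scores and of unscaled list means were chosen after the result was seen. Among lists that did not pass in either comparison with DSS_ICB, anorectal squamous epithelium had medians of 0.40 in DSS_ICB against DSS, -1.02 in DSS_ICB_Fp against DSS_ICB and -0.62 in DSS_ICB_Fp against DSS, over 5 members. Proliferation genes had -0.18 and -0.35 in the comparisons with DSS_ICB, crypt base genes -0.07 and 0.15, and circadian clock genes -0.22 and 0.21. Smooth muscle genes had 0.20 and -0.30, enteric neuron and glia genes 0.08 and -0.09, and adipocyte genes 0.13 and 0.18. Mitochondrially encoded genes had -0.18 and 0.10, endoplasmic reticulum stress genes -0.09 and -0.06, enteroendocrine genes 0.12 and -0.08 and tuft cell genes 0.14 and -0.24.

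Cytotoxic lymphocyte genes had medians of 0.26 in DSS_ICB against DSS and -0.40 in DSS_ICB_Fp against DSS_ICB, and regulatory T cell and checkpoint genes 0.07 and -0.28, where the ectonucleotidase Entpd1 was higher in the first (0.93) and lower in the second (-1.21) adjusted over the list alone. In the second, Cd274 (-1.0) was also lower and the transcription factor gene Tox (0.43) higher adjusted over the list alone. Among mast cell, eosinophil and type 2 genes, with medians of 0.03 and -0.16, the interleukin receptor gene Il1rl1 was likewise higher (1.80) and lower (-2.41) adjusted over the list alone. Interferon gamma genes had 0.03 and -0.28, and type I interferon genes -0.12 and -0.27. In the epithelial antimicrobial list, with medians of -0.07 and -0.06, members parted after gavage, with Saa3 (-3.29) and Lcn2 (-2.0) lower and the immunoglobulin receptor Pigr (1.55) and the inflammasome gene Nlrp6 (1.78) higher adjusted over the list alone. Median, mean and test differed in sign for the crypt base, antimicrobial and interferon gamma lists in DSS_ICB against DSS, for enteroendocrine and endoplasmic reticulum stress genes in DSS_ICB_Fp against DSS_ICB, and for tuft cell and enteric neuron genes in DSS_ICB_Fp against DSS. By the mean of unscaled log2 values per mouse, a measure beside the scaled score with which 0 lists passed, the adjusted exact permutation p was 0.042 in DSS_ICB_Fp against DSS_ICB for the absorptive colonocyte, neutrophil, inflammatory cytokine, fibroblast, endothelium, fetal-like repair and small intestine lists.

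Other splits of the libraries test whether the counts of genes arise from any grouping. For DSS_ICB against DSS, 2 of 100 splits, the real one included, gave as many genes (real 3, highest other 9), and 15 of 100 did by the count at an unadjusted p under 0.05. Data simulated with each group's own spread and no change gave a median of 3 calls (0 to 11), so chance is not excluded for a count of 3. For DSS_ICB_Fp against DSS_ICB, 4 of 100 did (real 19, highest other 720), and 2 of 100 did by the unadjusted count. The splits argue against chance for that count. The simulation with no change gave 0 to 16 calls in 20 draws, but it drew each gene independently of the others. In the fit of 2 groups 0 genes passed, so chance is not excluded. The split with 720 exchanged DSS_ICB 3 and DSS_ICB_Fp 4, and others gave 633 and 430, which points to a structure of the samples. For DSS_ICB_Fp against DSS the real count was 0, so all 100 of 100 splits had to give as many (highest other 0) and that count decides nothing. By the unadjusted count 53 of 100 gave as many, so chance is not excluded.

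As lists, neutrophil and inflammatory genes were higher in DSS_ICB and lower after gavage by the list test and by fry, but neither passed with an estimated correlation. Blood left in the tissue is argued against as the whole source, since with log2 Hbb-bs as a covariate the 27 genes of both lists kept 85.9% of their median change after gavage (78.2% to 100% leaving out 1 library, lowest without DSS_ICB 4), which went from -2.26 (median SE 0.436) to -1.94 (median SE 0.609), and for DSS_ICB against DSS from 1.68 to 1.53 (median SE 0.436 and 0.548). With limma 0 genes then passed in either comparison, with 479 and 1098 at an unadjusted p under 0.05. Whether the wider errors or the smaller changes ended the calls was not tested. A lower share of epithelium that raises all other cell types alike was tested against the pooled median of 168 members of 13 other lists. The neutrophil median lay 1.64 above it (95% bootstrap interval over genes 1.21 to 2.23). Without DSS_ICB 3 it lay 1.26 above (interval 0.881 to 1.70), and the interval stayed above 0 without each other library of the comparison. The neutrophil list had the highest median of these lists, and the test was chosen after the result was seen. An excess over the pooled lists was therefore likely in advance, and the test cannot exclude the explanation. Above the highest of the 13 other lists, erythroid, the neutrophil median lay by 0.147 (interval -0.245 to 2.19). Without DSS_ICB 3 it lay below the erythroid median (1.56 against 1.69), so neutrophil genes were not separated by size from these 7 blood genes. The intervals resample genes and not mice, so they do not measure the spread between mice. An effect of blockade and gavage, through more neutrophils or higher expression per cell, may underlie the pattern, and neither route was tested.

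The opposite directions of the 2 comparisons with DSS_ICB cannot be told apart from the effect of the shared DSS_ICB libraries. With separate DSS_ICB libraries for each comparison, 62.1% of the covariance was kept (mean -0.102, range -0.143 to -0.0154 over 20 divisions). That is over the bound of 50% set in advance for excluding the explanation, but the bound was too loose, since 57 of 1000 simulations with unchanged groups gave a mean as low. Against the explanation stand the covariance below 0 in all 20 divisions and the covariance with shared libraries, which 25 of 1000 of these simulations reached, although 59 of 1000 did in a simulation that could draw a library more than once. The tests therefore part, and the explanation stays open.

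Neutrophil and matrix scores, each centred on its group mean, had a Pearson r of 0.727 over the 15 mice (permutation p = 0.048) and a Spearman rho of 0.511 (permutation p = 0.145), with 100000 resamples. Without DSS_ICB 5 and DSS_ICB 3, the mice farthest from the median, r was 0.490, which leaves open how far the relation rests on those mice, and 1 such relation was computed.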
